A study of Mus musculus with 6 samples.

How the data were processed

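Total RNA of neural stem cell cultures from wild-type C57BL/6 mouse embryos at embryonic day 17.5 was measured on 6 Affymetrix arrays, 3 for the subventricular zone of the lateral ventricle and 3 for the third ventricle. Per the labels' protocols, dissociated cells grew in low-attachment dishes in serum-free medium with N2, B27, FGF at 20 ng/ml and EGF at 20 ng/ml. RNA was extracted with Trizol, and biotinylated cDNA was made with the NuGEN WT-Ovation Pico amplification from 500 pg to 50 ng of RNA. The deposited values are log2 expression per probe set, which the authors made with RMA in Affymetrix Expression Console 1.1, per the submitters' processing notes. RMA corrects background, normalizes the arrays to a shared distribution and summarizes the probes of a probe set. Further settings are not given in the sources used here. Amplification from so little RNA can add spread between arrays, and RMA values of dim probe sets are compressed toward the background, so differences of dim genes are understated.

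The table held 35556 probe sets. The platform annotation gave 1 gene symbol to 21789 of them and several to 1621, while 12146 were not listed and stay unnamed here. Of the symbols, 21698 matched the reference gene table of assembly GRCm38.p6, and 0 were changed by it. A gene was represented by its single-symbol probe set with the highest mean over the 6 arrays, which left 19938 genes, 999 of them with more than 1 probe set. No filter was set on dim genes. The files name no genome build, so no positions are given. Ddx3y had no single-gene probe set in this table and is not analysed here.

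Arrays were grouped by the region in their titles. Genes were compared as the third minus the lateral ventricle with limma 3.58.1 (lmFit and eBayes, default prior) in R 4.3.3, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The prior had 4.04 degrees of freedom and an SD of 0.14 on the log2 scale. Differences have moderated standard errors and 95% intervals, and means are given ± SD over 3 arrays. An exact permutation of 3 against 3 arrays cannot give a two-sided p below 0.1, so single genes rest on the limma model. The number of arrays limits the precision. The labels call the arrays biological replicates and the design text speaks of cultures from 3 independent females, but neither ties a replicate number to an animal, so p-values measure the spread between these cultures.

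Before the data were examined, 30 gene lists with 746 entries were fixed from textbook knowledge, and 679 of the entries were measured. They cover stem cell, regional patterning, glial, neuronal, ependymal, tanycyte, vascular, meningeal, blood, choroid plexus and pituitary genes, signalling pathways, cell cycle, metabolism, stress, interferon, matrix, ribosomal and sex-linked genes. Each list was tested with limma's camera at a preset correlation between genes of 0.01 and again with the correlation estimated from the data, with Benjamini-Hochberg adjustment over the 30 lists. Genes named in the text were chosen by a rule fixed at the same time. It takes the 12 largest passing differences in each direction among genes whose groups do not overlap, without predicted, olfactory, vomeronasal and histone genes. It adds up to 4 passing members of each list or, where none passed, the 2 with the highest mean. It also adds Xist and the Y-linked genes, and Nf1, Braf, Rheb, Erbb2, Egfr, Nes, Sox2, Nkx2-1, Rax and Olig2 whatever their result, and an item that is not reported here. Genes named only for the fit without lateral ventricle array 2 lie outside this rule and were chosen after their values were seen, and others outside it are said to be so.

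The steps were tested on simulated data for this comparison with 19938 genes, 200 of them changed. The fit recovered 23.9% of genes changed 1.5-fold, 89.6% of those changed 2-fold and 97.0% of those changed 4-fold. Of 146 calls, 6 were false. The simulated genes were independent and had the same spread in both groups, with SDs drawn from the fitted prior. In the real arrays a range above 1 was seen for 723 genes in the lateral and 18 in the third ventricle cultures. The simulated shares therefore need not hold for the real data. Where a group lay at or below the background gauge in all its arrays, the fold is given as a bound against the gauge. As that gauge, chosen after the values were seen, 1027 olfactory receptor genes had array medians of 3.39 to 3.51 and a 95th percentile of 5.03 to 5.16. Alternatives fixed beforehand covered the choice of probe set, a filter on the lowest 40% of genes, normalization, the variance prior, array weights, a block for the replicate number, a minimum fold of 1.2 and each array left out in turn. Chosen after seeing the data were the fits without lateral ventricle arrays 1 and 3, which leaves 1 lateral array that is assumed to vary like those of the third ventricle, with the cell cycle list mean as a covariate, with rank-based camera, and with Foxd1 taken out of the lists.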

Results

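Transcript levels were measured in neural stem cells grown from 2 regions of the embryonic mouse brain, the subventricular zone of the lateral ventricle and the third ventricle, with 3 arrays for each region. Neural stem cells in such cultures divide in response to FGF and EGF and can form neurons, astrocytes and oligodendrocytes. The median log2 value over all probe sets lay between 5.43 and 5.47 in the 6 arrays, and no 2 arrays held identical values. Over all genes, the arrays of the third ventricle correlated with each other at r = 0.995 in each of 3 pairs. Lateral ventricle array 2 stood apart from its group. It correlated with the third ventricle arrays at 0.991 to 0.992, and with lateral ventricle arrays 1 and 3 at 0.980 and 0.982. Genes are not independent replicates, so these correlations carry no p-value.

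**Figure D1:**
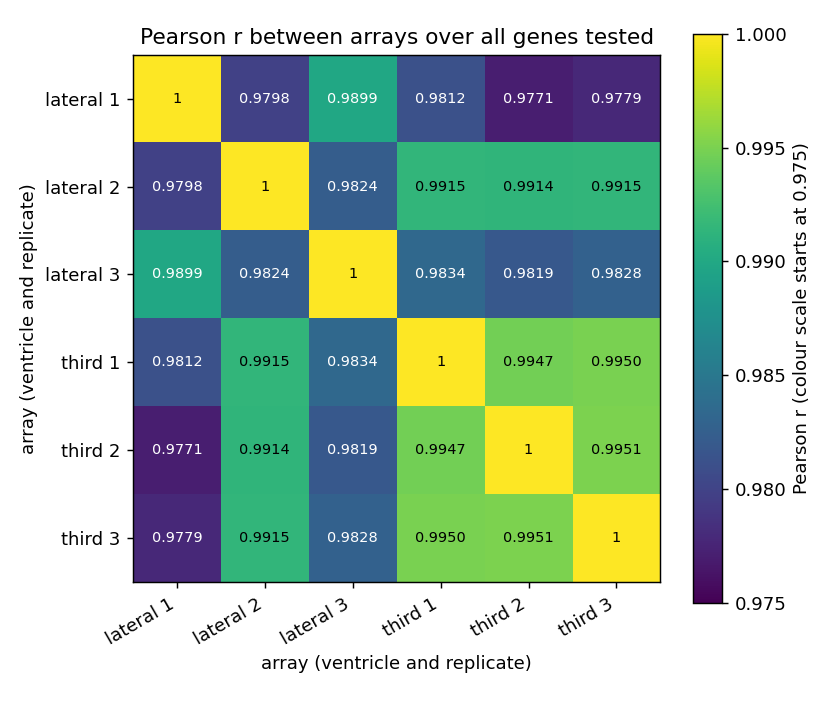
Pearson r between each pair of the 6 arrays over all genes tested, with arrays on both axes named by ventricle and replicate and a colour scale that does not start at 0. Lateral ventricle array 2 lies nearer the third ventricle arrays (0.991 to 0.992) than lateral ventricle arrays 1 (0.980) and 3 (0.982).

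The comparison asked which transcripts differ between stem cells of the third and the lateral ventricle. The gene with the lowest adjusted p was Foxd1, higher in the third ventricle cultures and a forkhead transcription factor of the developing hypothalamus. Its log2 value was 3.79 ± 0.10 (SD, n = 3) in lateral and 6.57 ± 0.12 (SD, n = 3) in the third ventricle cultures, a difference of 2.78 (limma, adjusted p = 7.34e-05). In all 3 lateral arrays it lay below the 95th percentile of the olfactory receptor genes used as a gauge of background, and against that percentile the third ventricle level was at least 2.75-fold higher. The adhesion molecule Chl1 was 5.78-fold higher (adjusted p = 0.0172), Fndc3c1, above the gauge in 1 of 3 lateral arrays, 4.68-fold (adjusted p = 0.0255) and Nr2f2, the nuclear receptor COUP-TFII, 3.47-fold (adjusted p = 0.0112). Lower in the third ventricle cultures were Cntn1, a contactin of the neural cell surface, and Pdgfra, the PDGF receptor found on oligodendrocyte progenitors. Cntn1 went from 8.37 ± 0.07 to 6.28 ± 0.16 (SD, n = 3), a log2 difference of -2.09 (adjusted p = 0.000524), and Pdgfra from 8.52 ± 0.26 to 6.73 ± 0.18 (SD, n = 3), a difference of -1.79 (adjusted p = 0.00707).

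In all, 46 of 19938 genes passed at an adjusted p below 0.05 in limma, 29 higher and 17 lower in the third ventricle cultures, and in each of the 46 the groups did not overlap. Groups did not overlap in 17.0% of all genes, against 10% by chance. At an unadjusted p below 0.05 there were 2521 genes, 1239 higher and 1282 lower. The count depended on single arrays. It was 25 without lateral ventricle array 1, 1644 without lateral ventricle array 2 and 20 without lateral ventricle array 3, and 7, 4 and 4 without the third ventricle arrays 1, 2 and 3. The 1644 genes (871 higher, 773 lower) included all 46, with the same signs. All 46 kept their sign in each fit that left out 1 array, but groups that do not overlap fix that outcome, so it is no separate support.

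Among the genes higher in the third ventricle cultures were further secreted and membrane proteins. Cacna2d3, an auxiliary subunit of voltage-gated calcium channels, differed by 1.54 on the log2 scale (SE 0.13), and Slit2, a guidance ligand of Robo receptors, by 1.53 (SE 0.18). Cbln1, a secreted organizer of synapses, differed by 1.44 (SE 0.18), the ferric reductase Cybrd1 by 1.42 (SE 0.13) and the zinc transporter Slc39a12 by 1.24 (SE 0.13). The small heat shock protein Cryab differed by 1.47 (SE 0.16), Plekhh2 by 1.26 (SE 0.17) and the adaptor Skap2 by 1.25 (SE 0.16). The adjusted p of these 8 genes lay between 0.00707 for Cacna2d3 and 0.0437 for Plekhh2. In the lateral arrays Slc39a12 lay above the background gauge in 0 of 3, which makes it at least 1.69-fold higher in the third ventricle cultures, Slit2 in 1 of 3, and Cacna2d3 and Cbln1 in 2 of 3.

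Among the genes lower in the third ventricle cultures, Nkain2 fell by 2.58 on the log2 scale (SE 0.26), Stk32a, a serine/threonine kinase above the background gauge in 1 of 3 arrays of the third ventricle, by 1.91 (SE 0.25) and the dynamin Dnm3 by 1.70 (SE 0.24). Plppr5, of the family of phospholipid phosphatase-related membrane proteins, went from 7.06 ± 0.04 to 5.41 ± 0.12 (SD, n = 3), with an adjusted p of 0.000949. Differences of -1.55 for the transmembrane protein Tmeff1, -1.51 for the protocadherin Pcdh15, -1.22 for Lhfpl3 and -1.20 for the retinaldehyde-binding protein Rlbp1 followed, then -1.14 for the zinc finger factor Myt1 and -1.04 for the LIM protein Fhl1. A second probe set of Nkain2 differed by only -0.03 and a second one of Pcdh15 by only -0.11, so those differences rest on 1 probe set each. Foxd1, Cntn1 and Plppr5 passed the threshold in all 18 alternatives of the fit.

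**Figure D2:**
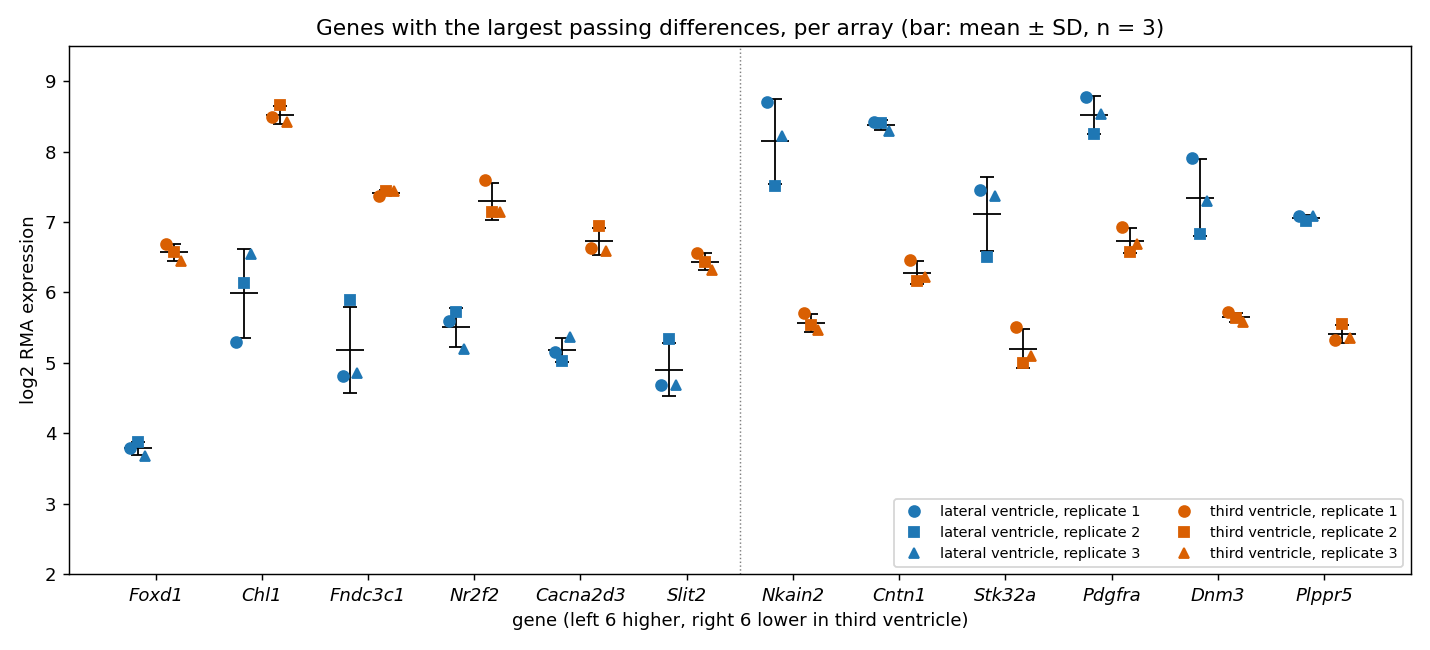
Log2 expression (vertical axis) of the 6 passing genes with the largest measured differences in each direction (horizontal axis), with predicted genes left out as in the rule for named genes. There is 1 point per array, blue for lateral and orange for the third ventricle, with symbols for the replicate and bars for mean ± SD (n = 3). Foxd1 lies at 3.79 ± 0.10 in lateral and 6.57 ± 0.12 in the third ventricle cultures, and Cntn1 at 8.37 ± 0.07 and 6.28 ± 0.16.

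Of the 30 gene lists, 7 passed at the preset correlation, 5 toward higher and 2 toward lower values in the third ventricle cultures. With an estimated correlation 0 of the 30 passed (lowest adjusted p = 0.392; 2 lists at an unadjusted p below 0.05), so each list result below depends on that setting. The estimates were 0.94 for cell cycle, 0.43 for hypoxia and glycolysis, 0.43 for stress, 0.21 for cholesterol and 0.15 for meningeal genes. They were 0.07 for oligodendrocyte and -0.02 for hypothalamic and diencephalic genes, against the preset 0.01. For the hypothalamic and diencephalic list the unadjusted camera p rose from 0.000221 to 0.0131, although its estimate lay below the preset. A higher correlation between its genes is thus not what removed that call, so the loss under this setting does not show that its genes move together. Without lateral ventricle array 2, the fit that called 1644 of the 19938 genes, further list members passed, and their numbers are given with each list. Such numbers are to be read against that share of all genes. That fit sets only lateral ventricle arrays 1 and 3 against the third ventricle, so lateral ventricle array 2 need not share a difference it calls. Among its 449 calls with a log2 difference of at least 1, array 2 lay nearer the lateral side at 75 (16.7%). A gene that passed only in that fit is therefore no regional difference shown by all lateral arrays. In each of the 23 lists that did not pass, leaving out 1 array moved the median by over 1.5 times or turned its sign. Of the 7 lists that passed, the median of 5 also moved by over 1.5 times, and 0 turned in sign.

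Genes that pattern the hypothalamus and diencephalon stood higher in the third ventricle cultures as a list. Of 34 measured, Foxd1 passed and 33 did not, 3 passed when adjusted over the list alone, 21 had a positive difference, and the median difference was 0.07. The adjusted p was 0.00166, and 0.392 with an estimated correlation. Without Foxd1 the adjusted p was 0.0174. Tbx3 and Nkx2-4 passed as well without lateral ventricle array 2, both higher. Nkx2-1, a ventral hypothalamic factor, differed by 0.25 (95% interval 0.03 to 0.47, adjusted p = 0.355) and Rax, a retinal and hypothalamic factor, by -0.05 (-0.38 to 0.28, adjusted p = 0.919), but Rax lay below the background gauge in 6 of 6 arrays, so its levels cannot be compared. Telencephalic patterning genes had a median of -0.03 over 22 genes (adjusted p = 0.625), 0 of which passed and 1 of which did over the list alone. Of the 22, 10 had a positive difference. Dlx1, Dlx5, Eomes, Neurog1, Lhx8, Sp8 and Isl1 lay below the background gauge in all 6 arrays, so the median says little about them. Nr2f1 (0.25) and Emx1 (0.14) had the highest mean signals of the list. Gsx2 (-0.84), Emx2 (-0.49) and Dlx2 (-0.35) were lower without passing, Gsx2 below the gauge in all 3 arrays of the third ventricle. Without lateral ventricle array 2 Gsx2 passed as lower. Midbrain, hindbrain and spinal cord patterning genes had a median of -0.00020 over 26 genes (adjusted p = 0.599), with Egr2 at 0.28 and Hoxb3 at -0.12. None of them passed, and En2 did as higher without lateral ventricle array 2.

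Oligodendrocyte lineage markers were lower as a list. Pdgfra and Lhfpl3 passed, 19 of the 21 measured did not, and 5 passed when adjusted over the list alone, all lower. The median difference was -0.21 and the adjusted p 0.000160, and 0.535 with an estimated correlation. Without lateral ventricle array 2, 5 members passed over all genes and the list kept its direction (adjusted p = 0.00179). Lateral ventricle array 1 carried much of the shift. Relative to each gene's mean, the list median was 0.33 in it against 0.09 in lateral ventricle arrays 2 and 3 and -0.16 to -0.08 in the third ventricle arrays, and without it the median difference was -0.12 (adjusted p = 0.000377). Olig2, a transcription factor of the lineage that cultured stem cells also express, differed by 0.09 (95% interval -0.14 to 0.33). Astrocyte markers had a median of 0.15 over 22 genes and did not pass (adjusted p = 0.142). None of them passed over all genes and 3 did over the list alone. Sparcl1 differed by 0.94 (adjusted p = 0.202) and Nfib by 0.38 (adjusted p = 0.348). The list median was 0.04 without lateral ventricle array 2, and 4 members passed, Sparcl1, Nfib and Id3 as higher and Apoe, the main lipid carrier of astrocytes, as lower, by -2.04 (adjusted p = 0.0210), against -1.35 (adjusted p = 0.409) over all arrays. The list passed without lateral ventricle array 1 (median 0.18, adjusted p = 0.00166). Neuronal markers had a median of -0.08 over 25 genes (adjusted p = 0.265), 0 of which passed and 1 over the list alone. Their members with the highest mean signals, Map2 and Tubb3, differed by 0.24 and -0.60. Tubb3 and Dcx passed without lateral ventricle array 2, both lower, while the median was then -0.0072 (adjusted p = 0.626), and -0.01 without array 1 of the third ventricle.

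No stem and progenitor marker passed between the regions. None of 22 did over all genes or over the list alone, and the median was -0.04 (adjusted p = 0.668). Fabp7 differed by 0.05 and the intermediate filament Vim by 0.19. Sox2 differed by -0.26 (95% interval -0.59 to 0.06, adjusted p = 0.476) and Nes, which encodes nestin, by 0.53 (-0.08 to 1.15, adjusted p = 0.449). The fit without lateral ventricle array 2 had 1 passing member in each direction, Nes at 0.86 (adjusted p = 0.0103) and the matrix protein Tnc at -0.79 (adjusted p = 0.0291). Over all arrays Tnc differed by -0.59 (adjusted p = 0.340). In lateral ventricle array 2 Nes lay at 7.70, above the third ventricle arrays (7.51 to 7.67), so its call came from lateral ventricle arrays 1 and 3.

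Cell cycle genes had the largest shift of any list, and it lay in 2 of the 3 lateral ventricle arrays. All 32 measured genes had a positive difference and the median was 1.12, but 0 passed, also over the list alone. The adjusted p of the list was 3.14e-17, and 0.632 with an estimated correlation. The estimate for this list, 0.94, lay far above the preset 0.01, so the lower p treats genes that move together as nearly independent. Relative to each gene's mean, the list median was -1.36, 0.56 and -0.89 in lateral ventricle arrays 1, 2 and 3, and 0.56, 0.53 and 0.58 in the third ventricle arrays. Top2a differed by 1.17 (adjusted p = 0.366) and Pcna by 0.56 (adjusted p = 0.381). Without lateral ventricle array 2, 31 of the 32 passed. The median difference was 0.72 without lateral ventricle array 1, with 0 passing. From lateral ventricle array 2 alone, 1 array with no replicate and a comparison chosen after seeing the data, the third ventricle arrays differed by a median of 0.0071.

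Cholesterol biosynthesis genes stood higher in the third ventricle cultures. Of 19 measured, 0 passed over all genes, 3 did over the list alone and 16 had a positive difference. The median was 0.23 and the adjusted p 2.10e-06, and 0.585 with an estimated correlation. Hmgcs1 differed by 0.19 and Cyp51 by 0.28. Relative to each gene's mean, the list median was -0.21, -0.01 and -0.15 in lateral ventricle arrays 1, 2 and 3 and 0.11 to 0.17 in the third ventricle arrays. Lateral ventricle array 2 thus lay nearer the third ventricle arrays but below them, and from it alone, with no lateral replicate, the median difference was 0.07. Without that array 4 of the 19 passed, all higher. Hypoxia and glycolysis genes had a median of 0.17 over 23 genes, with none passing, and an adjusted p of 0.0331, and 0.799 with an estimated correlation. The call was lost without lateral ventricle array 2 (median 0.13, adjusted p = 0.703; Higd1a higher and Vegfa lower), without lateral ventricle array 1 (median 0.10, adjusted p = 0.137) and without array 3 of the third ventricle (median 0.03, adjusted p = 0.516). It was kept without lateral ventricle array 3 (median 0.24, adjusted p = 5.21e-05) and without array 1 (0.24, adjusted p = 0.0189) or 2 (0.20, adjusted p = 0.000324) of the third ventricle, and from lateral ventricle array 2 alone the median difference was 0.33. It was also lost without the lowest 40% of genes (adjusted p = 0.1002), with quantile normalization again (0.0857), cyclic loess (0.0915) and array weights (0.391). Pgk1 differed by 0.17 and Hk1 by -0.05. Immediate early and stress genes were lower, with a median of -0.31 over 25 genes, none passing, and an adjusted p of 0.0175, and 0.799 with an estimated correlation. Asns, the asparagine synthetase, differed by -0.81 (adjusted p = 0.467) and Jun by 0.17. Asns passed without lateral ventricle array 2 (-1.37, adjusted p = 0.00182) and differed by 0.31 from that array alone. Without lateral ventricle array 2, 9 of the 25 passed, all lower, while the call was lost without lateral ventricle array 3 (median -0.19, adjusted p = 0.630) and without array 2 of the third ventricle (median -0.26, adjusted p = 0.0744). From lateral ventricle array 2 alone the median difference was 0.07, with no lateral replicate to test it.

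**Figure D3:**
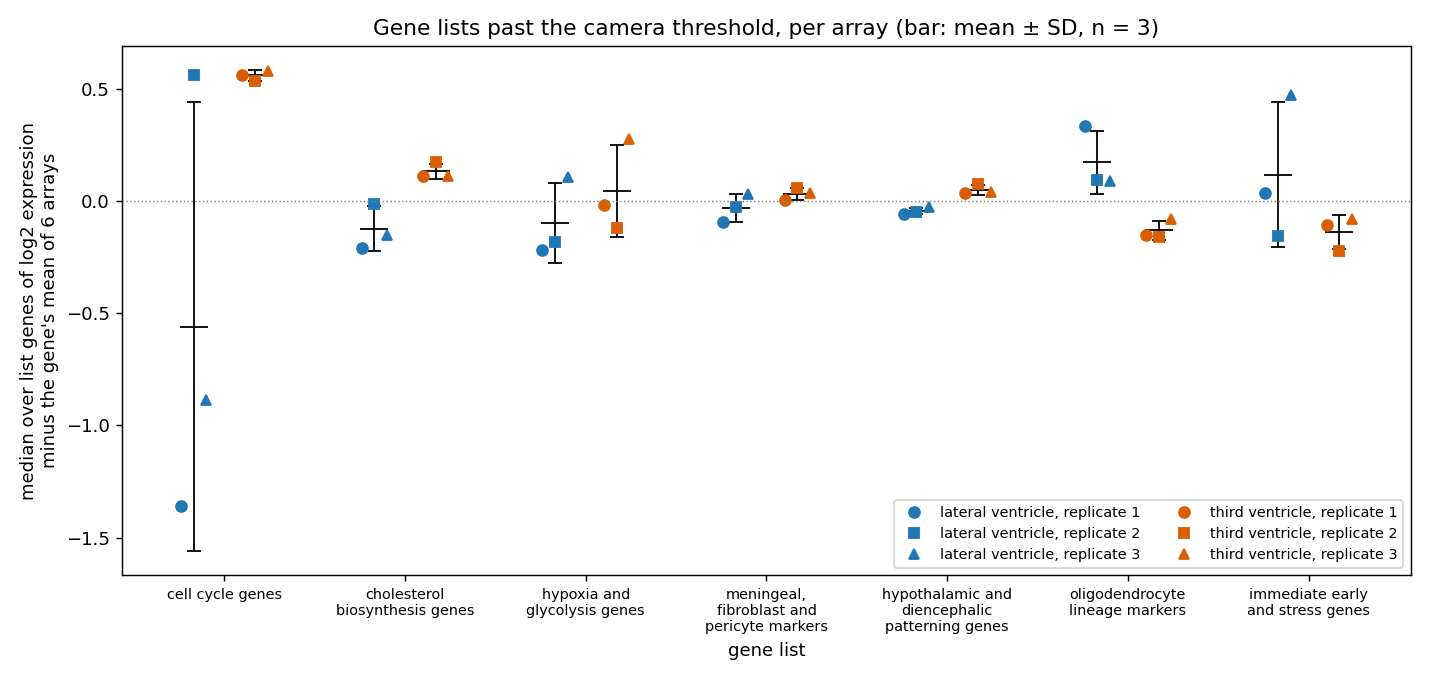
Median over the genes of each passing list of log2 expression minus the gene's mean of the 6 arrays (vertical axis), by list (horizontal axis), 1 point per array, with bars for mean ± SD (n = 3). In the cell cycle list, lateral ventricle array 2 (0.56) lies with the third ventricle arrays (0.53 to 0.58) and away from lateral ventricle arrays 1 (-1.36) and 3 (-0.89).

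None of the signalling lists passed. Ras, MAPK and PI3K-mTOR pathway genes had a median of -0.07 over 25 genes (adjusted p = 0.815), 0 of which passed and 1 over the list alone. The Ras regulator Nf1 differed by -0.11 (95% interval -0.32 to 0.10), the kinase Braf by -0.22 (-0.44 to 0.01) and the GTPase Rheb by -0.11 (-0.37 to 0.14), with Nras at 0.14 and Rps6 at 0.02. In the fit without lateral ventricle array 2, 5 of the 25 passed, Pik3r1 as higher (0.45, adjusted p = 0.0299) and Tsc1 (-0.69, adjusted p = 0.00470), Pik3cb, Eif4ebp1 and Rictor as lower. Over all arrays Pik3r1 differed by 0.34 (adjusted p = 0.327) and Tsc1 by -0.48 (adjusted p = 0.346). Receptor tyrosine kinase genes had a median of -0.03 over 33 genes (adjusted p = 0.723), and only Pdgfra passed, with 7 over the list alone, 2 higher and 5 lower. Egfr differed by 0.36 (0.07 to 0.66, adjusted p = 0.338) and Erbb2 by 0.32 (0.11 to 0.54, adjusted p = 0.287). Without lateral ventricle array 2, 2 passed as higher and 6 as lower. Egfr (adjusted p = 0.0193) was among the higher, and among the lower were Ddr2, a collagen receptor, at -1.41 (adjusted p = 0.000772), Ntrk3 at -0.74 (adjusted p = 0.00503) and Fgfr2 at -0.79 (adjusted p = 0.0173). Over all arrays these differed by -0.83 (Ddr2, adjusted p = 0.468), -0.67 (Ntrk3, adjusted p = 0.0790) and -0.49 (Fgfr2, adjusted p = 0.454). In lateral ventricle array 2 Ddr2 lay at 4.86, below the background gauge of that array (5.16). In the third ventricle arrays it lay at 5.06 to 5.31, near their gauge of 5.07 to 5.12, so these levels cannot be ranked and the size of its difference is uncertain. Notch pathway genes had a median of 0.04 over 26 genes (adjusted p = 0.625; Rbpj -0.14, Maml2 -0.04), and Hedgehog pathway genes -0.13 over 15 (adjusted p = 0.321; Ptch1 0.22, Disp1 -0.16). Neither had a passing member, also over the list alone, but without lateral ventricle array 2 Dner passed as higher and Hey1, Dll3 and Hhip as lower. Wnt pathway genes had a median of -0.04 over 35 genes (adjusted p = 0.815; Fzd3 0.16, Lrp6 -0.22), and BMP and TGF-beta pathway genes 0.0034 over 31 (adjusted p = 0.825; Bmpr2 0.04, Smad5 0.31). Each had 1 member that passed over the list alone, and without lateral ventricle array 2 Wnt5a and Id3 passed as higher and Bmp4 as lower.

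Of 8 lists of markers of other cell types, 1 passed. It was the list of meningeal, fibroblast and pericyte markers, which stood higher in the third ventricle cultures (median 0.10 over 22 genes, adjusted p = 0.00555, and 0.632 with an estimated correlation). Foxd1 is a member of that list and its only passing one, also over the list alone. Without it the adjusted p was 0.0593, while the median was still 0.09. The list lost its call without lateral ventricle array 1 (median 0.06, adjusted p = 0.0693), and its median was 0.06 without array 2 (adjusted p = 0.0158) or array 3 (adjusted p = 0.00878) of the third ventricle. Ependymal and ciliary genes (median 0.03 over 24, adjusted p = 0.310), tanycyte markers (-0.0078 over 16, adjusted p = 0.858), microglia and macrophage markers (-0.03 over 21, adjusted p = 0.903) and endothelial markers (-0.03 over 17, adjusted p = 0.625) did not pass. Neither did erythroid genes (0.02 over 9, adjusted p = 0.493), choroid plexus markers (0.04 over 15, adjusted p = 0.310) or pituitary markers (-0.04 over 14, adjusted p = 0.815). No member of these 7 lists passed over all genes, and 1 tanycyte and 1 choroid plexus marker passed over the list alone. The tanycyte marker Scn7a and the choroid plexus marker Sostdc1 passed without lateral ventricle array 2, both higher, with Scn7a below the background gauge in the 5 arrays of that fit. The members with the highest mean signals differed by 0.30 (Rfx3), 0.28 (Ccdc39), -0.70 (Vcan, adjusted p = 0.213), -0.07 (Adm), -0.04 (Trem2), -0.21 (Cd68), -0.05 (Mfsd2a), 0.26 (Plvap), 0.36 (Tfrc), 0.10 (Alas2), 0.09 (Kcnj13), -0.07 (Otx2), 0.02 (Ghrhr) and -0.06 (Lhb).

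The remaining lists did not pass either. Cyclin-dependent kinase inhibitors and p53 targets had a median of 0.17 over 13 genes (adjusted p = 0.310; Cdkn1b -0.10, Ccng1 0.26), and interferon response and antigen presentation genes -0.06 over 22 (adjusted p = 0.668; B2m -0.12, Psmb9 0.16). Ribosomal protein genes had a median of -0.02 over 22 (adjusted p = 0.825; Rps20 0.0081, Rps4x 0.0073). None of their members passed, but without lateral ventricle array 2 Cdkn2c and Cdkn2d did as higher and Gadd45a and Sesn2 as lower. The median of the first list was then 0.06, and that of the interferon list was 0.02, and 0.05 without array 1 of the third ventricle. Extracellular matrix and adhesion genes had a median of 0.01 over 41 genes (adjusted p = 0.586), with Cntn1 the only passing member and 7 over the list alone, 4 higher and 3 lower. With lateral ventricle array 2 left out, 3 passed as higher and 4 as lower. The median, mean and test of a list differed in sign for the midbrain and hindbrain, Wnt, BMP and TGF-beta, microglia, endothelial, and matrix lists, none of which passed.

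The labels give all samples as female, which Xist, the RNA of the inactive X chromosome, and the Y-linked genes can check. Xist lay between 9.13 and 10.22 in the 6 arrays. The Y-linked genes Eif2s3y (7.71 to 8.26), Kdm5d (7.42 to 7.80) and Uty (6.48 to 7.11) also lay above the 95th percentile of the olfactory receptor genes in 6 of 6 arrays, while Zfy1, Zfy2 and Usp9y did so in 0 of 6. None of these genes passed between regions, and the list of 7 measured genes had a median of -0.12 (adjusted p = 0.668).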

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

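The fits without both lateral ventricle arrays 1 and 3, with the cell cycle list mean as a covariate, with rank-based camera and with lists without Foxd1 were chosen only after the result was seen. Against 46 genes (29 higher, 17 lower), the count stayed within 1.5 times, from 45 to 59, with the mean of all probe sets (45), without the lowest 40% of genes (46), with quantile normalization again (47), median centring (54), trend and robust priors (56), the replicate block (57) and cyclic loess (59). Without lateral ventricle arrays 1 and 3 it was 59, with 29 of the 46 among them, but only 1 lateral array then remains, the spread comes from the third ventricle arrays alone, and the lone array is assumed to vary like them. It was 4 (2 higher, 2 lower) with all 35556 probe sets tested singly, and 17 (11 higher, 6 lower) with a minimum fold of 1.2, a stricter null. It was 158 (89 higher, 69 lower) with array weights, which gave lateral ventricle array 2 the lowest weight (0.426), and 24 (15 higher, 9 lower) with the covariate, which kept 15 of the 46. Leaving out each array in turn gave 4 to 1644 genes, 2 to 871 higher and 2 to 773 lower. Of these fits, those without array 2 or 3 of the third ventricle gave the lowest count, and that without lateral ventricle array 2 gave the highest. A count of 4 was also reached with all arrays when the probe sets were tested singly. All of the 46 genes that a setting tested kept their sign in it. For the fits that left out arrays this was fixed beforehand, since the groups did not overlap in these genes. Of the fall to 4, the number of tests is only part, since the p-values of the 19938 genes adjusted for 35556 tests would leave 23, and the prior also had fewer degrees of freedom (2.69 against 4.04). No scaling moved the median of all genes, -0.018, by over 0.1. Dim genes near the background gauge limit what can be seen, since their differences are compressed.

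Replicate numbers occur in both groups, but deviations from the group mean correlated at 0.24, 0.111 and 0.068 for arrays 1, 2 and 3 of the same number, so not every pair passed 0.1 and the numbers are not taken to pair the arrays. With the replicate block, 57 genes passed, 30 higher and 27 lower, and 36 of the 46 were among them. Every array correlated best with the one of its own number, a hint from the data and not from the design.

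With an estimated correlation 0 lists passed in place of 7. With other settings 4 to 7 of the 7 lists still passed. The list lost without the lowest 40% of genes (median 0.18), with quantile normalization again (0.15), cyclic loess (0.14) and array weights (0.16) was that of hypoxia and glycolysis genes, and the meningeal list was lost with the covariate (0.048), without Foxd1 (0.091) and without lateral ventricle arrays 1 and 3 (0.057). The cell cycle list was lost with the covariate (0.027), which is made from it, and without lateral ventricle arrays 1 and 3 (0.0071). Astrocyte markers passed as well without lateral ventricle array 1 (median 0.18), with the covariate (0.20) and, with 1 lateral array left, without lateral ventricle arrays 1 and 3 (0.14), where cyclin-dependent kinase inhibitors and p53 targets did too (0.17). The list of immediate early and stress genes, which passed, turned in direction and lost its call in 2 fits. These were the fit without lateral ventricle arrays 1 and 3 (median 0.070) and that with the covariate (median -0.021, with the test toward higher values), and the cause was not tested.

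Among results that passed on neither side, a change of sign was seen in 27 of 65 named genes and in lists with small differences, and the cause was not tested. Cyclic loess gave Fabp7 -0.0019, Rps6 -0.032, Rps20 -0.046, Rps4x -0.047 and Usp9y 0.00043. Array weights gave Maml2 0.018, Mfsd2a 0.013 and Rps4x -0.0068, and quantile normalization gave Bmpr2 -0.0029. Without lateral ventricle arrays 1 and 3 the differences were Pcna -0.0046, Top2a -0.053, Ptch1 -0.039, Disp1 0.023, Adm 0.52, Otx2 0.15, Hk1 0.0029, Asns 0.31, B2m 0.016, Psmb9 -0.086, Eif2s3y 0.076, Rheb 0.027, Nes -0.12 and Olig2 -0.044. With the covariate they were Pcna -0.022, Top2a -0.068, Smad5 -0.0056, Adm 0.32, Otx2 0.17, Hk1 0.028, Asns 0.18, B2m 0.024, Psmb9 -0.11, Eif2s3y 0.034, Nes -0.14 and Olig2 -0.042.

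For lists, whose direction is that of the test and whose value is the median, the fit without lateral ventricle arrays 1 and 3 turned microglia and macrophage (-0.14), midbrain and hindbrain (-0.077), Ras, MAPK and PI3K-mTOR (-0.036), receptor tyrosine kinase (0.0012), ribosomal protein (0.025) and telencephalic (0.017) genes. The covariate turned BMP and TGF-beta (-0.013), erythroid (-0.014), microglia and macrophage (-0.12), midbrain and hindbrain (-0.089), receptor tyrosine kinase (-0.0057), ribosomal protein (0.021) and telencephalic (0.0045) genes. Without the lowest 40% of genes the midbrain and hindbrain (-0.057) and pituitary (-0.021) lists turned, and with rank-based camera the tanycyte list (-0.0078). Over the fits that left out 1 array, differences ranged from -0.015 to 0.11 for Fabp7, -0.015 to 0.062 for Rps6, -0.14 to 0.12 for Maml2, -0.37 to 0.42 for Adm, -0.15 to 0.050 for Trem2, -0.19 to 0.031 for Mfsd2a, -0.023 to 0.22 for Kcnj13 and -0.22 to 0.076 for Otx2. They ranged from -0.011 to 0.069 for Ghrhr, -0.10 to 0.019 for Hk1, -0.030 to 0.043 for Rps20, -0.025 to 0.041 for Rps4x, -0.10 to 0.0056 for Usp9y and -0.16 to 0.065 for Rax. List medians ranged from -0.0041 to 0.020 for BMP and TGF-beta, -0.063 to 0.024 for endothelial, -0.042 to 0.044 for microglia and macrophage, 0.0052 to 0.076 for Notch, -0.062 to 0.018 for pituitary, -0.056 to -0.026 for Ras, MAPK and PI3K-mTOR, -0.050 to 0.00010 for ribosomal protein and -0.055 to 0.063 for tanycyte genes. For the other lists that did not pass they ranged from 0.043 to 0.18 for astrocyte, 0.0024 to 0.055 for choroid plexus, 0.059 to 0.21 for cyclin-dependent kinase inhibitor and p53, 0.0042 to 0.058 for ependymal, -0.0058 to 0.046 for erythroid, -0.0088 to 0.064 for matrix, -0.14 to -0.075 for Hedgehog, -0.096 to 0.047 for interferon, -0.027 to 0.064 for midbrain and hindbrain, -0.086 to -0.019 for stem and progenitor, -0.088 to -0.0072 for neuronal, -0.026 to 0.018 for receptor tyrosine kinase, -0.050 to -0.022 for telencephalic, -0.069 to -0.00084 for Wnt and -0.14 to -0.028 for X-inactivation and Y-linked genes.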

Other observations

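All tests in this part were chosen only after the result was seen, except that of imprinted genes, which was written before its result but after Peg3 and Zim1 had been seen. The 3 lateral ventricle cultures differed from each other more than those of the third ventricle did. The range over 3 arrays was above 1 on the log2 scale for 723 genes in the lateral and 18 in the third ventricle cultures. Genes named here were chosen for a wide lateral range among those with a range below 0.5 in the third ventricle arrays, after their values were seen. Their narrow range in the third ventricle arrays was thus set by the choice. The cationic amino acid transporter Slc7a3 lay at 8.62, 5.60 and 9.42 in lateral ventricle arrays 1, 2 and 3 and at 5.28 to 5.73 in those of the third ventricle. Nupr1, a stress-induced nuclear protein, lay at 10.13, 6.57 and 10.35, against 6.81 to 6.85. Cth, which makes cysteine from cystathionine, lay at 6.58, 5.37 and 7.98, the mitochondrial folate enzyme Aldh1l2 at 8.25, 6.00 and 8.49, the heat shock gene Hspa1a at 7.13, 5.71 and 8.08, and the damage-induced Gadd45a at 7.97, 6.57 and 8.92.

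DNA replication and mitosis genes ran the other way in the same arrays. The replication helicase subunit Mcm3 lay at 5.03, 7.75 and 6.26 in lateral ventricle arrays 1, 2 and 3 and at 7.36 to 7.57 in those of the third ventricle. Rrm2, a subunit of ribonucleotide reductase, lay at 6.79, 9.40 and 7.59, against 9.11 to 9.38, the chromatin remodeller Hells at 6.01, 8.84 and 7.18, and the mitotic kinase Ttk at 6.38, 8.98 and 7.22. Not every gene with a wide lateral range set array 2 apart. Cd93 lay at 5.46, 7.15 and 7.89, and Dgkk at 5.51, 5.98 and 7.80.

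Lateral ventricle array 2 resembled the third ventricle arrays, and its cell cycle level was theirs. A mislabelled array of the third ventricle is argued against, since at 16.7% of 449 genes that separate the other lateral arrays from those of the third ventricle it lay nearer the lateral side, against at most 0.654% for a held-out array of the third ventricle. A mixture of cells of both regions in 1 proportion is argued against by 39 genes within 0.25 of the way from the lateral side on the linear scale, against 0 in any held-out array, while 331 lay within 0.25 of the other side. An earlier test by the spread of positions (0.333 against at most 0.205) had been undecided. A difference in growth state between cultures is a candidate explanation of the cell cycle shift and was not tested independently, since the distance of array 2 from the mean of the third ventricle in that list, 0.0031, is the value that raised it, and a difference by region stays open too.

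The oligodendrocyte lineage list passed as lower in the third ventricle cultures at the preset correlation, but not with an estimated one (camera, adjusted p = 0.535). Of its 21 measured members 2 passed, and lateral ventricle array 1 carried much of the shift. Fewer oligodendrocyte progenitors in the third ventricle cultures may be its source. The 14 lineage genes other than Pdgfra that lay above the background gauge in all 3 lateral ventricle arrays had a median difference of -0.24 (SD 0.49 over these genes), from -1.35 for Gpr17 to 0.17 for Olig1, against -1.79 for Pdgfra, and 12 of the 14 were lower. This does not decide, because neural stem cells grown in FGF and EGF also express several of these genes. The shift was not in Pdgfra alone, since Lhfpl3 also passed (-1.22). Gpr17, Ugt8a (-1.01) and Sox10 (-0.74) were lower without passing, while Olig1 and Olig2 (0.09) were higher. The number of progenitors and their level of these transcripts cannot be told apart here, and a regional difference was not tested separately.

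Xist and Y-linked transcripts occurred together in cultures given as female, while Zfy1, Zfy2 and Usp9y lay in the background. Cells of both sexes in each culture are a candidate source, but the level of Xist, Eif2s3y, Kdm5d and Uty above the 95th percentile of olfactory receptor genes in 6 of 6 arrays is what raised it and does not test it. A limit of 0.2 over the arrays had been set for each Y minus X difference, for X-linked copies as the only signal on the Y probe sets. The difference ranged by 0.46 for Eif2s3y, 0.75 for Kdm5d and 1.34 for Uty, the last mostly through lateral ventricle array 1 (-1.87, against -0.99 to -0.53 in the others). That limit was no wider than the median range of a gene over 3 arrays, 0.29 in the lateral and 0.20 in the third ventricle cultures. The spread of probe sets alone could thus pass it, and these values do not decide on cross-hybridization of X-linked copies. The largest range of the 3 Y-linked genes themselves was 0.627. Whether the label describes the embryos or the mother is not given in the sources used here.

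Splits of the 6 arrays into 3 and 3 number 10, too few for a share under 0.05. The real split gave 46 genes and the highest of the others 0, so 1 of the 10 gave as many. It gave 7 lists and the highest of the others 4, so 1 of the 10 gave as many lists.

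The imprinted gene Peg3 (1.16, adjusted p = 0.0316) passed toward the third ventricle, and its neighbour in the same imprinted domain, Zim1, did not pass (adjusted p = 0.0756) and lay below the background gauge in all 3 lateral ventricle arrays. Both lie outside the rule for named genes. The hypothesis that imprinted genes as a group may stand higher there was tested on 26 others, of which 13 had a positive difference. Camera gave p = 0.429, and p = 0.426 with an estimated correlation, so the hypothesis was not borne out for the rest of the group, and it was not excluded either.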
